A study of Homo sapiens with 9 samples.

How the data were processed

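RNA was measured in 9 libraries of telomerase-immortalized gingival keratinocytes, 3 each of untreated, IFN-beta and IFN-lambda cells, after 24 h of stimulation of cells short of confluence, per the labels' protocols. RNA was extracted with a column kit and libraries were made with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes the tools were FastQC 0.10.1, STAR 2.6, HTSeq 0.10.0 and DESeq2, with the genome build hg38. The annotation release, the strand setting and the rule for overlapping genes are not given in the sources used here. Reads of a gene and of its antisense partner, and reads shared by overlapping genes, therefore cannot be told apart with certainty. Genes named by the rule given below with more than 5% of their exon bases shared on the same strand are marked as such. Genes named outside that rule were not checked for such sharing.

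The deposited values are counts of reads per gene, made with HTSeq per the submitters' processing notes, and are whole numbers that sum to a different total in each library, so they were taken as not normalized. Each of the 9 per-library tables held the same counts as the table of the series. The deposited count tables also carry summary lines, which stayed out of library sizes and tests: reads in no feature were 10.3% to 12.0% of all lines, ambiguous reads 1.49% to 1.74% and reads with more than 1 alignment 24.8% to 31.6%, leaving 55.2% to 63.2% in genes. Reads with several alignments were left out of gene counts, so genes with near-identical copies (HLA, IFIT, OAS, KRT6 and histone genes) are less certain. Of 44452 gene identifiers, 44392 were found in GENCODE 29 (GRCh38), which gave symbols and positions, and 60 were not. The counts covered 19695 of 19951 protein-coding identifiers and 16 of 7629 lincRNA identifiers of that release. Mitochondrially encoded genes and cytosolic ribosomal protein genes were not analysed here, and the list of mitochondrially encoded mRNA was not tested. Every CPM is therefore scaled to a library total without these abundant genes.

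Totals in genes were 18584202 to 24768505 counts per library, with 20393 to 21028 genes detected. The floor was set at 3 counts, or 0.121 to 0.161 CPM per library. The 50 most abundant genes took 13.7% to 15.2% of counts.

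Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group (minimum count 10, minimum total 15), which kept 15127 genes, TMM normalization, and the quasi-likelihood test (glmQLFit, glmQLFTest) with all 9 libraries in 1 fit and a mean per group. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another tool is named. The common dispersion was 0.00111, a biological coefficient of variation of 3.3%. CPM values were scaled by the TMM factors.

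The design, the groups and the 32 gene lists (25 of them on the treatment and the tissue, the rest on other cell types and RNA quality) were fixed before the data were examined. Lists with at least 3 tested genes, 29 in all, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the estimated correlation, calls were lost where the text prints that p at 0.05 or more, and the other calls held. Some estimates lay far above the preset, such as 0.446 for the cell-cycle list with IFN-beta. Camera p-values with the preset can therefore be far too small. The lowest adjusted p in camera with the estimated correlation was 0.0138 with IFN-beta, 0.00252 with IFN-lambda and 0.0108 between the interferons. The rotation test fry asks whether a list's genes move on balance in a direction and does not compare them with other genes. It was run once per comparison, on all tested genes and libraries, and called 20 lists higher and 4 lower with IFN-beta, 23 and 3 with IFN-lambda, and 5 and 17 between the interferons. Median, mean and test differed in sign only for lists that camera did not call: with IFN-beta the endothelial list (median 0.05, mean -0.05); with IFN-lambda the negative regulators (-0.02, 0.22), the tryptophan and polyamine (-0.01, 0.04), basal (-0.00, 0.04), antimicrobial (-0.005, 0.07), endothelial (0.06, -0.01) and leukocyte (-0.06, 0.30) lists; between the interferons the negative regulators (0.00, -0.04), ER stress (-0.02, 0.01) and histone (0.01, -0.00) lists, and the leukocyte list, whose median and mean were -0.08 and -0.07 with a positive test.

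Genes were named by a rule set together with the design. It took the 5 genes with the highest and the 5 with the lowest change in each comparison (called, at least 1 CPM on average, groups apart, with a symbol), the called members of each main list with the largest rise and fall, the most abundant member of each check list, and 14 interferon pathway genes whatever their values. Some genes that the rule or a list takes in are not reported here. Members that are named because a list had few exceptions (such as TAP2, CCNE1 and ANKRD37), and further examples of a list outside the rule, were chosen after their values were seen.

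The overlap of the responses was set against independent lists and against 20 simulated draws. In each draw all libraries, the untreated ones included, were drawn without any effect, and both other groups were compared with the drawn untreated libraries. The mean log2-CPM of the antiviral list was compared between groups with an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3.

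The scripts were tested on simulated counts of 15127 genes with known changes. For IFN-beta against untreated, 62% of genes changed 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 100% at 4-fold were recovered (50 genes each), and 4.2% of calls were false. For IFN-lambda against untreated the shares were 66%, 82%, 98% and 100%, with 7.6% of calls false. A list of 40 genes raised 1.5-fold was found in both simulations (adjusted p = 6.52e-138 and 1.03e-137 in camera) and an unchanged list was not (0.701 and 0.5). Genes were drawn independently there, so the simulations cannot tell how often correlated genes give false list calls.

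The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, an adjusted p under 0.01 and each library left out in turn. Added after the data were seen were a correction for GC content and exon length (values for 99.9% of tested genes), the same with the block, and all libraries thinned to the smallest. The correction also takes out each library's mean deviation in log2-CPM. A shift in the balance of higher and lower genes with it therefore cannot be put down to GC content and length alone. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and figures.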

Results

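Gene expression was measured by RNA sequencing in TIGK cells, an established line of human gingival (gum) keratinocytes immortalized with telomerase. The 9 libraries fell into 3 groups of 3 libraries: untreated cells, cells given interferon beta (IFN-beta, a type I interferon) and cells given interferon lambda (IFN-lambda, a type III interferon), both for 24 h. The labels give no doses, so the interferons were compared as they were given. The comparisons ask which genes of gingival epithelial cells respond to each interferon and how the responses differ. The libraries held 18584202 to 24768505 counts in genes, and a floor of 3 counts equalled 0.121 to 0.161 CPM (counts scaled to a common library total of 1e6), which covers counting error only. In each of the 9 pairs of libraries within a group the counts differed by more than sampling noise (chi-square per gene 1.65 to 3.91). The labels call the replicates separate without naming separate cultures, so p-values measure the spread between these libraries, which may be technical. Of the tested genes, 15127 in all, levels are given below as mean CPM ± SD (n = 3 per group) and changes as log2 values with an SE. That SE was derived from the F value of the quasi-likelihood test and the unshrunk change, not from the SDs printed beside it. The test shares information on spread across genes, so an SE can be smaller than a gene's SDs imply. MX2, for example, stood at 6.57 ± 2.91 CPM in untreated libraries and had an SE of 0.11 with IFN-beta. Gene positions are those of GENCODE 29 on GRCh38.

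The comparison of IFN-beta with untreated cells asks what a type I interferon changes. Antiviral genes rose, and IFI44L, an interferon-induced gene (ENSG00000137959, chromosome 1, 78619922 to 78646145), went from 10.8 ± 3.89 to 319.6 ± 14.1 CPM. Genes of DNA replication and mitosis fell, and MKI67, which encodes the proliferation marker Ki-67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), went from 318.6 ± 36.8 to 171 ± 2.14 CPM. Genes of keratinocyte differentiation rose, and DSG1, a desmosomal cadherin of differentiating layers (ENSG00000134760, chromosome 18, 31318089 to 31357029), went from 25.3 ± 3.06 to 54.5 ± 3.42 CPM. Hypoxia-regulated genes rose too, and NDRG1 went from 649.7 ± 7.98 to 1734 ± 45.1 CPM.

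Among antiviral effectors, 49 of 51 genes rose with IFN-beta (49 when adjusted over the list alone) and 0 fell. The median log2 change was 1.93 and the adjusted p in camera 2.09e-68 (adjusted p = 0.0138 with an estimated correlation). ZC3HAV1 was among those not called. IFI44L rose by 4.90 (SE 0.10), and MX2, a dynamin-like restriction factor, by 4.65 (SE 0.11, adjusted p = 1.86e-19 in edgeR). MX1, its paralog, rose by 3.28 (SE 0.08). All 6 measured genes of the ISG15 conjugation pathway rose (6 when adjusted over the list alone, median 2.06, adjusted p = 2.36e-13 in camera), led by ISG15, a ubiquitin-like modifier, from 38.1 ± 4.83 to 442.4 ± 8.80 CPM. Guanylate-binding proteins rose in 5 of 6 genes (5 over the list alone, median 0.71, adjusted p = 5.59e-05), and GBP1 rose by 1.40 (SE 0.05). Of the nucleic acid and microbial sensors, 13 of 22 rose and 1 fell (14 and 1 over the list alone, median 0.61, adjusted p = 2.25e-08). DDX58, which encodes the RNA sensor RIG-I, rose by 2.57 (SE 0.09). CGAS, a DNA sensor and the member called lower, had a log2 change of -0.28, which was -0.18 with an adjusted p of 0.0601 without untreated replicate 1 and 0.0557 without IFN-beta replicate 2 (range over all alternatives 0.000378 to 0.0601).

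Signalling genes were divided. STAT and IRF factors rose in 11 of 15 genes (12 over the list alone, median 0.36, adjusted p = 6.20e-09 in camera), among them IRF7 by 2.35 (SE 0.05) and IRF1 by 0.36 (SE 0.08). IRF9 rose by 1.88 (SE 0.12), but 48.4% of its exon bases lie on the same strand within another annotated gene, so its level is uncertain. The list of interferon receptor chains and kinases did not pass (IFNGR1 of 9 higher, 1 over the list alone, adjusted p = 0.548 in camera and 0.0505 in fry). IFNLR1, the specific chain of the IFN-lambda receptor (ENSG00000185436, chromosome 1, 24154157 to 24187959), stood at 30.8 ± 0.0565 CPM in untreated and 30.8 ± 1.67 CPM in IFN-beta libraries, and IFNAR1 at 62.8 ± 1.79 and 64.2 ± 1.78 CPM. IFNAR2 and IL10RB were low, at 5.39 ± 0.470 and 1.74 ± 0.365 CPM in untreated cells, and share 44.2% and 38.1% of their exon bases with a readthrough gene. Negative regulators of JAK-STAT signalling did not pass camera's comparison with other genes (5 of 17 higher, namely USP18, SOCS1, SOCS2, PIAS3 and PTPN6, and SOCS4 and PTPN11 lower, the same over the list alone, adjusted p = 0.357, at most 0.484 in camera's alternatives). The rotation test fry, which tests a list against no change, called them higher (adjusted p = 5.57e-04). SOCS4, at -0.20, had an adjusted p of 0.0231 that was 0.0941 without untreated replicate 2 and 0.178 without IFN-beta replicate 2 (range over all alternatives 0.00355 to 0.178). USP18, which removes ISG15 and dampens type I signalling, rose by 1.82 (SE 0.08) and SOCS1 by 0.60 (SE 0.09).

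Antigen presentation by MHC class I rose in 20 of 21 genes (20 over the list alone, median 0.69, adjusted p = 6.89e-22 in camera), with TAP2 not called. PSMB9, an immunoproteasome subunit (ENSG00000240065, chromosome 6, 32844136 to 32859585) with 5.7% of its exon bases shared with another gene, rose by 1.33 (SE 0.13) from 4.68 ± 0.413 CPM. HLA-G rose by 1.73 (SE 0.23), though HLA genes share reads with their paralogs. The MHC class II list did not pass (CTSS and IFI30 of 10 higher, HLA-DPB1 lower, the same over the list alone, adjusted p = 0.643 in camera and 0.244 in fry), and CTSS, a lysosomal protease, rose by 0.90 (SE 0.27). HLA-DPB1, at -0.31, had an adjusted p of 0.0102 that was 0.0538 without untreated replicate 3 (range over all alternatives 0.00269 to 0.0538). Interferon-type chemokines and cytokines rose in 4 of 8 genes, CXCL10, CCL5, TNFSF10 and IL15RA (4 over the list alone, adjusted p = 0.0212 in camera, adjusted p = 0.122 with an estimated correlation, 0.0545 without untreated replicate 3, in a range of 0.00014 in fry to 0.122). CXCL10, a T-cell chemokine, stood at 0.122 ± 0.174 CPM in untreated and 0.540 ± 0.0589 CPM in IFN-beta libraries. The untreated mean lay at the floor, and the log2 change of 2.19 was 4.25 without untreated replicate 1 (1.61 to 4.25 leaving out a library), so its size is uncertain. Its adjusted p of 0.0165 became 0.0692 without untreated replicate 2 and 0.0718 without untreated replicate 3, in a range of 0.000172 to 0.0718 over all alternatives. Inflammatory cytokines rose in 7 of 17 genes (7 over the list alone, adjusted p = 0.00551, adjusted p = 0.0511 with an estimated correlation), and IL1A rose by 0.61 (SE 0.17), or 0.93 without untreated replicate 2. NF-kB feedback genes did not pass camera (6 of 15 higher, 6 over the list alone, adjusted p = 0.0578), except without untreated replicate 2 (0.0457) or IFN-beta replicate 1 (0.0497). The range in camera's alternatives was 0.0457 to 0.112. They also passed in fry (adjusted p = 5.14e-04). TNFAIP3, an NF-kB inhibitor, rose by 0.96 (SE 0.11). Immune checkpoint ligands rose in 5 of 9 genes (5 over the list alone, adjusted p = 9.41e-04, adjusted p = 0.0736 with an estimated correlation), with LGALS9, 5.1% of whose exon bases lie in another gene, up by 2.76 (SE 0.11).

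Cell-cycle genes fell in 35 of 36 genes (36 over the list alone, adjusted p = 1.50e-34 in camera, adjusted p = 0.0311 with an estimated correlation), with CCNE1 not called and a median of -0.61. RRM2, a ribonucleotide reductase subunit, fell by 0.99 (SE 0.05), with 20.2% of its exon bases shared with another gene. MCM10, a replication factor, fell by 1.16 (SE 0.10). The replication-dependent histone list, a check on polyadenylated RNA, rose in 7 of 9 genes (9 over the list alone, median 0.79, adjusted p = 1.13e-06), and the immediate-early list, a check on handling, in 11 of 17 (13 over the list alone, median 0.31, adjusted p = 7.90e-06). H1F0, the most abundant gene of the histone list and a linker histone not tied to replication, rose by 0.39 (SE 0.04), and MYC, of the immediate-early list, by 0.25 (SE 0.04). Histone genes share reads with near-identical copies.

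Keratinocyte differentiation genes rose in 26 of 47 genes and fell in 4 (26 and 5 over the list alone, median 0.42, adjusted p = 2.76e-08 in camera). KRT6C, a keratin of activated epithelium with close paralogs, rose by 1.55 (SE 0.09) and DSG1 by 1.11 (SE 0.08), while KRT4, a keratin of oral mucosa, fell by 0.78 (SE 0.06). Basal and hemidesmosome genes rose in 17 of 21 genes and CAV1 fell (17 and 1 over the list alone, adjusted p = 9.00e-09), with COL17A1, a hemidesmosome collagen, from 1606 ± 24.8 to 2541 ± 46.0 CPM. Epithelial junction genes rose in 17 of 31 and fell in 5 (18 and 5 over the list alone, adjusted p = 8.82e-07, adjusted p = 0.0559 with an estimated correlation), with GJA1, the gap junction protein connexin 43, up by 1.02 (SE 0.06) and TJP1 down by -0.27 (SE 0.04). Antimicrobial proteins rose in 9 of 16 genes (9 over the list alone, median 0.46, adjusted p = 0.00102), among them PGLYRP4 by 0.88 (SE 0.16) and RNASE7, a secreted ribonuclease, by 0.66 (SE 0.17). The histone and immediate-early check lists rose alongside these groups, as above, so the checks on RNA and handling did not come out clear. Whether the differentiation, hypoxia and ER stress changes hold such a difference between the groups was not tested.

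Hypoxia genes rose in 17 of 18 genes (17 over the list alone, median 0.47, adjusted p = 2.42e-15 in camera), with ANKRD37 not called. ER stress genes rose in 15 of 19 (15 over the list alone, adjusted p = 3.49e-06), with DDIT3, 8.0% of whose exon bases lie in another gene, up by 0.76 (SE 0.06). Cell death genes rose in 16 of 32 and FAS, TNFRSF10D and BAX fell (16 and 4 over the list alone, adjusted p = 7.86e-04): XAF1 rose by 3.89 (SE 0.11) and TNFRSF10D, a decoy receptor for TRAIL, fell by 1.04 (SE 0.08). Nuclear genes of oxidative phosphorylation fell in 17 of 29 (20 over the list alone, median -0.15, adjusted p = 4.05e-07, adjusted p = 0.0698 with an estimated correlation), with NDUFA4 down by -0.26 (SE 0.04). Sterol synthesis genes fell in 15 of 24 and rose in 4 (16 and 4 over the list alone, median -0.13, adjusted p = 0.00979, adjusted p = 0.398 with an estimated correlation). Tryptophan and polyamine enzymes fell in 4 of 8, namely ODC1, SRM, SMS and AMD1, and SAT1 was higher (5 and 1 over the list alone, adjusted p = 0.0212, adjusted p = 0.184 with an estimated correlation). SAT1, at 0.13, had an adjusted p of 0.022 that was 0.0805 without untreated replicate 3 and 0.056 without IFN-beta replicate 1 (range over all alternatives 0.0084 to 0.0805), and ODC1, the first enzyme of polyamine synthesis, fell by 0.54 (SE 0.04).

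In all, 2779 genes were higher and 2979 lower with IFN-beta, 38.1% of those tested. The balance depended on the setting. It was 2377 higher and 3711 lower with the GC and length correction, which also recentred each library. The higher genes were the more numerous with a minimum of 1 CPM (3042 and 2672) and with RLE factors (2889 and 2869). They were so too without untreated replicate 1 (2725 and 2356), untreated replicate 3 (2604 and 2410) or IFN-beta replicate 2 (2467 and 2165). At least 2-fold changes were fewer, with 230 higher and 31 lower, and 84.8% of called genes changed by less than 1.5-fold. The 3 IFN-beta libraries did not overlap the 3 untreated ones in 48.0% of genes, where chance gives 10%. The count at least 2-fold lower was 17 with DESeq2, 15 with a minimum of 1 CPM in 3 libraries and 52 without a filter on low counts. Of 29 lists tested, 18 were higher and 4 lower in camera, and 14 and 1 with an estimated correlation.

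**Figure D1:**
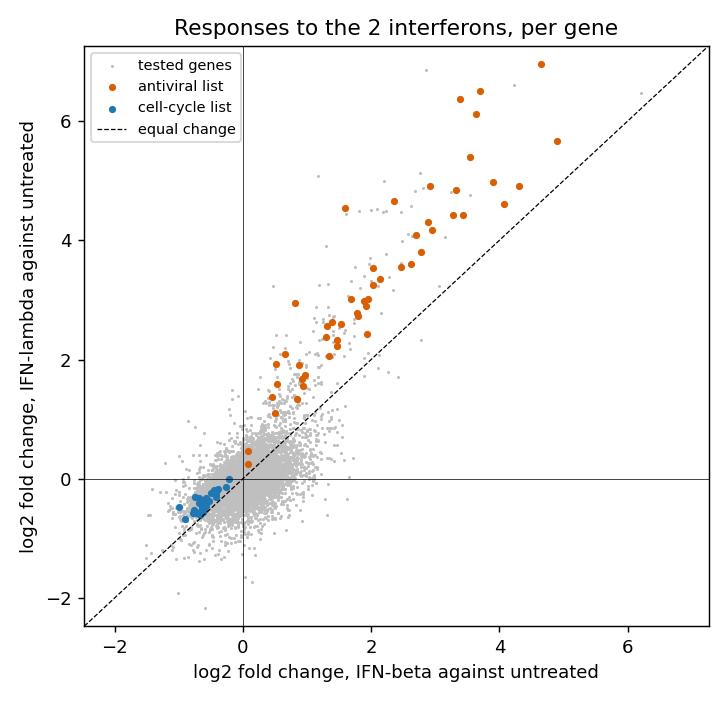
Log2 change of each tested gene with IFN-beta (x axis) and with IFN-lambda (y axis), each against the 3 untreated libraries. Grey points are tested genes, orange the antiviral list and blue the cell-cycle list, and the dashed line marks equal change; the antiviral medians were 1.93 on the x axis and 3.01 on the y axis.

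The comparison of IFN-lambda with untreated cells asks what a type III interferon changes. Antiviral genes rose, and MX2 (ENSG00000183486, chromosome 21, 41361943 to 41409390) went from 6.57 ± 2.91 to 803.6 ± 19.8 CPM. RSAD2, which encodes the antiviral enzyme viperin (ENSG00000134321, chromosome 2, 6865806 to 6898239), went from 2.68 ± 1.02 to 217 ± 11.2 CPM. MHC class I genes rose, with PSMB9 from 4.68 ± 0.413 to 45.1 ± 5.45 CPM. Cell-cycle genes fell, with MKI67 from 318.6 ± 36.8 to 199.3 ± 13.8 CPM. ACO1, a cytosolic aconitase that also binds iron-responsive RNA elements (ENSG00000122729, chromosome 9, 32384603 to 32454769), went from 83.3 ± 3.15 to 22.1 ± 0.729 CPM.

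All 51 antiviral effectors rose with IFN-lambda (51 over the list alone, median 3.01, adjusted p = 1.24e-125 in camera, adjusted p = 0.00252 with an estimated correlation). MX2 rose by 6.96 (SE 0.11, adjusted p = 1.01e-23 in edgeR), CMPK2, a mitochondrial nucleotide kinase next to RSAD2, by 6.51 (SE 0.11), RSAD2 by 6.37 (SE 0.12) and TRIM22 by 6.12 (SE 0.08), the last with 10.7% of its exon bases shared with another gene. All 6 genes of the ISG15 pathway rose (6 over the list alone, median 3.30, adjusted p = 1.33e-22), with ISG15 at 1595 ± 105 CPM. The guanylate-binding proteins rose in all 6 genes (6 over the list alone, median 1.90, adjusted p = 4.20e-11), with GBP1 up by 2.42 (SE 0.05). Sensors rose in 14 of 22 genes and MAVS was lower (15 and 1 over the list alone, median 0.72, adjusted p = 2.59e-18), with DDX58 up by 4.11 (SE 0.09). MAVS had a log2 change of -0.12, and its adjusted p of 0.00915 became 0.0523 without untreated replicate 3 and 0.0555 without IFN-lambda replicate 3 (range over all alternatives 0.00425 to 0.0555).

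STAT and IRF factors rose in 11 of 15 genes (12 over the list alone, median 0.56, adjusted p = 1.05e-16 in camera), with BATF2, a transcription factor of interferon responses, up by 5.00 (SE 0.17) and IRF1 by 1.28 (SE 0.07). The receptor and kinase list did not pass camera (IFNGR1 and JAK1 of 9 higher, 3 over the list alone, adjusted p = 0.43, at most 0.544 in camera's alternatives). In fry it was higher (adjusted p = 0.0343). IFNLR1 stood at 30.6 ± 1.62 CPM. Negative regulators did not pass camera (3 of 17 higher, SOCS7 lower, the same counts over the list alone, adjusted p = 0.484, at most 0.544 in camera's alternatives). In fry they were higher (adjusted p = 7.78e-05), though their median was -0.02. USP18 rose by 3.20 (SE 0.07) and SOCS1 by 1.12 (SE 0.09). MHC class I genes rose in 21 of 21 (21 over the list alone, median 1.35, adjusted p = 3.91e-47). MHC class II genes rose in 2 of 10 (2 over the list alone), with CTSS up by 1.71 (SE 0.23). That list did not pass camera (adjusted p = 0.121, at most 0.3 in camera's alternatives) and was higher in fry (adjusted p = 0.00745). Interferon-type chemokines rose in 6 of 8 genes and IL18BP was lower (6 and 1 over the list alone, adjusted p = 1.44e-05), with CXCL10 up by 4.48 (SE 0.49) to 2.68 ± 1.101 CPM. Since untreated CXCL10 lay at the floor, 0.122 ± 0.174 CPM, the size of its change is uncertain, and it was 6.53 without untreated replicate 1. The IL18BP change of -0.28 had an adjusted p of 0.0409, which was 0.0729 with DESeq2, 0.0521 with a minimum of 1 CPM, 0.0506, 0.0802 and 0.134 without untreated replicates 1, 2 and 3, and 0.207 without IFN-lambda replicate 3 (range over all alternatives 0.0035 to 0.207). Inflammatory cytokines rose in 9 of 17 (9 over the list alone, adjusted p = 8.59e-06), with CXCL8, a neutrophil chemokine, up by 1.42 (SE 0.25). NF-kB feedback genes rose in 4 of 15 (4 higher and 1 lower over the list alone, adjusted p = 0.00679), with TNFAIP3 up by 1.07 (SE 0.10) and BIRC3 by 0.78 (SE 0.07). NFKB1 was the member called lower, at -0.12 (-0.07 without untreated replicate 1). Its adjusted p of 0.0462 passed 0.05 no longer in 14 alternatives, among them 0.273 without untreated replicate 1 and 0.218 without IFN-lambda replicate 2 (range over all alternatives 0.00465 to 0.273). Checkpoint ligands rose in 7 of 9 (7 over the list alone, adjusted p = 4.32e-07), with LGALS9 up by 5.12 (SE 0.08).

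Cell-cycle genes fell in 35 of 36 genes (35 over the list alone, median -0.39, adjusted p = 1.43e-29 in camera, adjusted p = 0.0346 with an estimated correlation), and RRM2 fell by 0.47 (SE 0.05). The histone check list rose in 8 of 9 genes (9 over the list alone, adjusted p = 5.77e-09) and the immediate-early list in 9 of 17 (11 over the list alone, adjusted p = 1.82e-05). As with IFN-beta, a difference in RNA or handling therefore stays open and was not tested. Differentiation genes did not pass as a list (14 of 47 higher, 8 lower, 15 and 9 over the list alone, adjusted p = 0.313 in camera and 0.257 in fry). KRT6B rose by 1.17 (SE 0.07), KRT4 fell by 1.19 (SE 0.06) and DSG1 stood at 25.5 ± 2.62 CPM. Basal genes did not pass camera (3 of 21 higher, 5 lower, 4 and 5 over the list alone, adjusted p = 0.506, at most 0.903 in camera's alternatives) and were higher in fry (adjusted p = 0.0375), though their median was -0.003. COL17A1 rose by 0.57 (SE 0.03). Junction genes rose in 12 of 31 and fell in 4 (13 and 5 over the list alone, adjusted p = 0.00201, adjusted p = 0.208 with an estimated correlation), with CLDN1 up by 0.44 and CGN down by -0.44. Of the antimicrobial proteins only ADM among 16 tested was called (1 over the list alone), up by 0.47 (SE 0.04). That list had an adjusted p of 0.491 in camera (at most 0.596 in camera's alternatives) and was higher in fry (adjusted p = 0.0366), though its median was -0.005.

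Hypoxia genes rose in 16 of 18 genes (16 over the list alone, median 0.28, adjusted p = 1.04e-13 in camera), with CA9, carbonic anhydrase 9, up by 0.96 (SE 0.13). ER stress genes rose in 11 of 19 (12 over the list alone, adjusted p = 1.81e-07) and cell death genes in 20 of 32, with TNFRSF10D lower (21 and 2 over the list alone, adjusted p = 2.76e-15). Sterol genes rose in 13 of 24 (13 and 1 lower over the list alone, median 0.12, adjusted p = 4.19e-06, adjusted p = 0.184 with an estimated correlation), with STARD4, a sterol carrier, up by 0.64 (SE 0.04). Oxidative phosphorylation genes fell in 6 of 29 and NDUFA9 rose (7 and 1 over the list alone, adjusted p = 0.0494, adjusted p = 0.469 with an estimated correlation). In 8 alternatives the list no longer passed, among them 0.0634 and 0.134 without untreated replicates 1 and 2, 0.0566 without IFN-beta replicate 1 or 2, 0.195 without IFN-lambda replicate 1 and 0.102 with a minimum of 1 CPM (range 0.0157 to 0.469). NDUFA9 shares 10.6% of its exon bases with other genes. The tryptophan and polyamine list did not pass camera (2 of 8 higher, 2 lower, the same over the list alone, adjusted p = 0.87, at most 0.995 in camera's alternatives) and was higher in fry (adjusted p = 0.0219), though its median was -0.01. WARS, the tryptophanyl-tRNA synthetase, rose by 0.84 (SE 0.03) and ODC1 was down by -0.36 (SE 0.03). TNFRSF10D fell by 1.34 (SE 0.08), and NANOS1 by 1.35 (SE 0.13).

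In all, 1702 genes were higher and 2019 lower with IFN-lambda, 24.6% of those tested, with 291 at least 2-fold higher and 42 at least 2-fold lower, and groups that did not overlap in 37.3% of genes, where chance gives 10%. The balance was 1544 higher and 2297 lower with upper-quartile factors and 1621 and 2647 with the GC and length correction. Higher genes were the more numerous with a minimum of 1 CPM (1850 and 1791), without a filter (1843 and 1796), with RLE factors (1834 and 1827), DESeq2 (1462 and 1439) or only the 6 libraries compared (1755 and 1731). They were so too without untreated replicate 1 (1819 and 1695), untreated replicate 3 (1426 and 1425) or IFN-beta replicate 2 (1849 and 1829). The 2019 lower genes were 1292 at an adjusted p under 0.01. The count at least 2-fold lower was 21 with DESeq2, 21 at an adjusted p under 0.01, 19 with a minimum of 1 CPM and 64 without a filter. Of 29 lists, 17 were higher and 2 lower in camera, and 15 and 1 with an estimated correlation. The 2 were also 1 in each other setting in which the oxidative phosphorylation list lost its call.

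**Figure D2:**
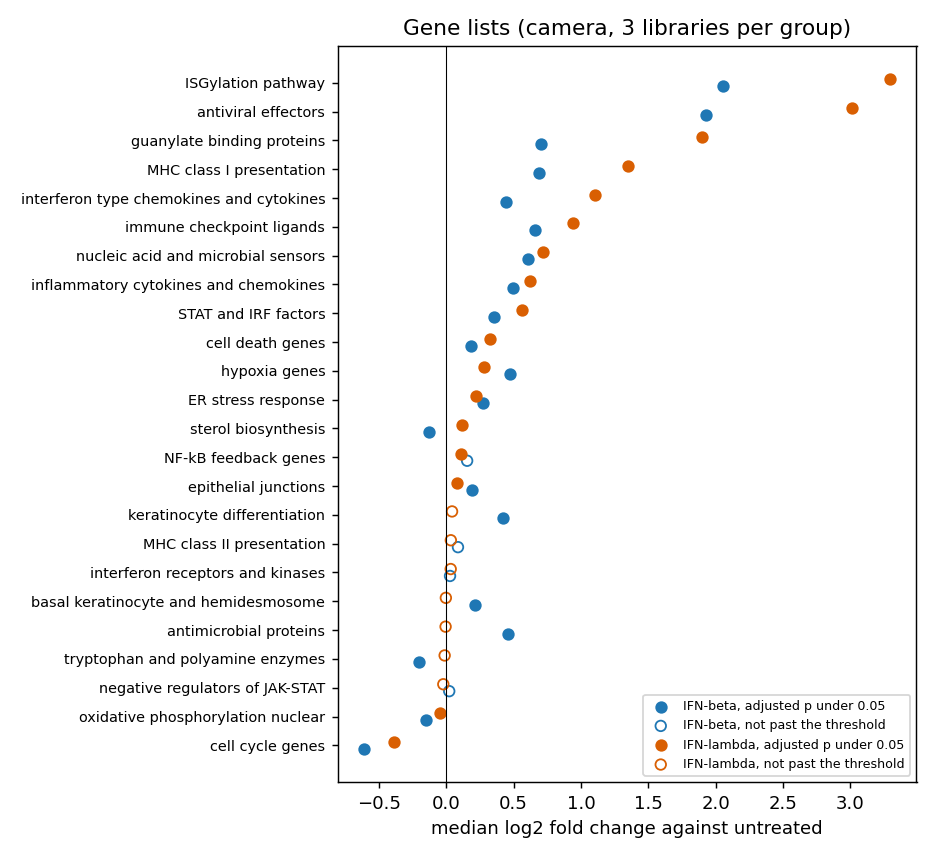
Median log2 change of the tested genes of each main list (at least 3 tested) with IFN-beta (blue) and with IFN-lambda (orange), each against untreated cells; the x axis is the median log2 change. A filled point passed camera at an adjusted p under 0.05 and an open point did not; the antiviral list had the medians 1.93 with IFN-beta and 3.01 with IFN-lambda.

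Both responses shared genes. With both interferons 1075 genes were higher and 1211 lower, where independent lists of these sizes would share 313 and 398. Simulated unchanged groups set against the same drawn untreated libraries shared 0.1 and 0.0 on average. Such draws hold few calls by design, so those shared counts cannot tell how much overlap the shared controls add. The 1211 genes were 1748 with the GC and length correction and 1839 with the replicate block added. The log2 changes correlated across genes at 0.715 (Pearson; Spearman 0.529), against 0.515 in the simulation, and genes are not independent replicates. Their covariance was 0.1145 against 0.0128 simulated, a difference of 0.1018. The 3 untreated libraries could not be split with at least 2 on each side, so part of the excess over independent lists may come from the shared controls, which the simulation holds and those lists leave out. Of the genes higher with both, 333 rose more with IFN-lambda and 201 more with IFN-beta in the direct test, the latter 127 without IFN-lambda replicate 2. Of those lower with both, 403 fell more with IFN-beta and 71 more with IFN-lambda. In opposite directions, 110 genes were higher with IFN-beta and lower with IFN-lambda and 60 the reverse.

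The direct comparison of the interferons asks how their effects differ. Antiviral genes were higher with IFN-lambda: RSAD2 stood at 217 ± 11.2 CPM against 27.5 ± 4.71 CPM with IFN-beta, and IFIT2, which encodes an RNA-binding antiviral protein (ENSG00000119922, chromosome 10, 89283694 to 89309276), at 653.4 ± 21.3 against 84.7 ± 3.19 CPM. IFIT genes are close paralogs, and IFIT2 shares 8.7% of its exon bases with another gene. Differentiation genes were higher with IFN-beta, with DSG1 at 54.5 ± 3.42 against 25.5 ± 2.62 CPM. So were antimicrobial proteins, with RNASE7 at 2.90 ± 0.187 against 1.71 ± 0.119 CPM.

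Of the 51 antiviral effectors, 50 were higher with IFN-lambda than with IFN-beta (51 over the list alone), by a median log2 difference of 1.08 (adjusted p = 5.29e-78 in camera, adjusted p = 0.0108 with an estimated correlation). Their mean log2-CPM per library was 7.07 to 7.13 with IFN-beta, 8.30 to 8.34 with IFN-lambda and 4.85 to 5.13 in untreated cells, and the exact two-sided permutation p was 0.1 for each pair of groups, the smallest that 3 against 3 allows. RSAD2 was higher with IFN-lambda by 2.98 (SE 0.08, adjusted p = 2.30e-18 in edgeR), IFIT2 by 2.95 (SE 0.05), BATF2 by 2.79 (SE 0.13) and SLC15A3, a lysosomal peptide transporter, by 2.52 (SE 0.19). All 6 genes of the ISG15 pathway were higher with IFN-lambda (6 over the list alone, adjusted p = 3.19e-15), as were 20 of 21 MHC class I genes (20 over the list alone, adjusted p = 1.51e-25). So were 14 of 22 sensors with 2 lower (the same over the list alone, adjusted p = 2.60e-09) and 18 of 32 cell death genes with 2 lower (20 and 2 over the list alone, adjusted p = 5.47e-10). PSMB9 was higher with IFN-lambda by 1.94 (SE 0.09), NLRC5, the MHC class I transactivator, by 1.56 (SE 0.05) and APOL3 by 1.54 (SE 0.11). NLRP1, an inflammasome sensor of keratinocytes, went the other way and was higher with IFN-beta by 0.71 (SE 0.08).

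Other groups higher with IFN-lambda lost their call with an estimated correlation. These were the guanylate-binding proteins (6 of 6 genes, 6 over the list alone, adjusted p = 7.32e-06, adjusted p = 0.0518 with an estimated correlation) and the STAT and IRF factors (7 of 15, 7 over the list alone, adjusted p = 6.32e-06, adjusted p = 0.103 with an estimated correlation). IRF9 did not differ past the threshold (0.15, SE 0.10, adjusted p = 0.268), except without IFN-lambda replicate 3 (0.0332) and with the GC and length correction and the replicate block (0.0486), in a range of 0.0332 to 0.692. The interferon-type chemokines were higher in 5 of 8 genes and lower in 1 (the same over the list alone, adjusted p = 0.00257, adjusted p = 0.08 with an estimated correlation). The checkpoint ligands were higher in 3 of 9 (3 over the list alone, adjusted p = 0.00243, adjusted p = 0.109 with an estimated correlation) and the tryptophan and polyamine enzymes in 5 of 8 with 1 lower (the same over the list alone, adjusted p = 0.00261, adjusted p = 0.123 with an estimated correlation). WARS was higher with IFN-lambda by 0.80 (SE 0.03). Sterol genes were higher in 20 of 24 and lower in 1 (the same over the list alone, adjusted p = 4.20e-11, adjusted p = 0.0924 with an estimated correlation), with INSIG1, a sterol-regulated inhibitor of sterol synthesis, higher by 0.42 (SE 0.04). Cell-cycle genes were higher with IFN-lambda in 31 of 36 (33 over the list alone, median difference 0.21, adjusted p = 1.97e-12, adjusted p = 0.14 with an estimated correlation), and RRM2 by 0.52 (SE 0.05). Oxidative phosphorylation genes were higher in 12 of 29 and lower in 1 (13 and 1 over the list alone, adjusted p = 2.13e-04, adjusted p = 0.175 with an estimated correlation).

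Differentiation genes were higher with IFN-beta than with IFN-lambda in 27 of 47, with TGM1 lower (27 and 1 over the list alone, median 0.30, adjusted p = 1.83e-11 in camera). Basal genes were higher in 15 of 21 and lower in 3 (15 and 3 over the list alone, adjusted p = 1.61e-07) and antimicrobial proteins in 8 of 16 (9 over the list alone, adjusted p = 5.77e-04). DSG1 was higher with IFN-beta (adjusted p = 7.34e-11 in edgeR), KRT15, a basal keratin, by 0.63 (SE 0.04) and RNASE7 by 0.76 (SE 0.16). TGM1, at a log2 difference of -0.12, had an adjusted p of 0.0147, which was 0.0757 without IFN-lambda replicate 3 (range over all alternatives 0.000486 to 0.0757). Junction genes were higher in 15 of 31 and lower in 4 (the same over the list alone, adjusted p = 8.89e-06, adjusted p = 0.104 with an estimated correlation), with GJA1 higher by 0.81 (SE 0.06) and EPCAM lower at -0.25. Hypoxia genes were higher in 10 of 18 and lower in 1 (the same over the list alone, adjusted p = 1.06e-04, adjusted p = 0.105 with an estimated correlation), with NDRG1 higher by 0.85 (SE 0.05). PALMD, a cytosolic protein named for its likeness to paralemmin, was higher with IFN-beta by 1.41 (SE 0.15), and WFDC5 by 1.36 (SE 0.26).

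The other lists did not pass camera in the direct comparison: receptors (JAK1 of 9 higher with IFN-lambda, 0 over the list alone, adjusted p = 0.964), negative regulators (3 and 3 of 17, the same over the list alone, adjusted p = 0.793), MHC class II (3 of 10 higher with IFN-lambda, 3 over the list alone, adjusted p = 0.337) and inflammatory cytokines (4 of 17 higher and 1 lower with IFN-lambda, the same over the list alone, adjusted p = 0.116). Nor did NF-kB feedback (1 and 1 of 15, the same over the list alone, adjusted p = 0.803) and ER stress (4 and 4 of 19, the same over the list alone, adjusted p = 0.894). In fry 4 of these lists were higher with IFN-lambda. These were the negative regulators (adjusted p = 0.00147, with a median near 0), MHC class II (0.0293), inflammatory cytokines (0.00278) and NF-kB feedback (0.0436). The highest adjusted p of these lists in camera's alternatives was 0.867, 0.495, 0.211 and 0.902, in the same order. JAK1 had an adjusted p of 0.038, which was 0.06 with upper-quartile factors and lay between 0.0522 and 0.147 without untreated replicate 3 or any of the 6 interferon libraries in turn (range over all alternatives 0.014 to 0.147). The histone list (1 and 1 of 9, adjusted p = 0.863) and the immediate-early list (4 higher and 2 lower with IFN-beta of 17; 5 and 4 over the list alone, adjusted p = 0.293) did not pass camera either.

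In all, 2415 genes were higher and 2684 lower with IFN-beta than with IFN-lambda, 33.7% of those tested, with 82 at least 2-fold higher and 125 at least 2-fold lower, and groups that did not overlap in 45.5% of genes, where chance gives 10%. The balance was 2062 higher and 2835 lower with the GC and length correction, and it turned with upper-quartile factors (2646 and 2417) and with only the 6 libraries compared (2644 and 2639). Of 382 genes raised at least 2-fold by either interferon, 112 rose at least 2-fold more with IFN-lambda and 25 at least 2-fold more with IFN-beta. Further counts took genes called with either interferon, not called in that direction with the other, and different in the direct test. For IFN-beta these were 1232 higher and 1187 lower genes, the latter 722 without IFN-beta replicate 2. For IFN-lambda they were 434 higher and 518 lower genes, the latter 336 with DESeq2. Genes called in opposite directions with the interferons were not taken out of these counts. The 2415 genes were 1513 at an adjusted p under 0.01, and the 82 were 54 there, 40 with DESeq2 and 38 with a minimum of 1 CPM. Of 29 lists, 5 were higher and 13 lower with IFN-beta in camera, and 3 and 5 with an estimated correlation.

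Lists of other cell types did not pass camera in any comparison, though single members were called. The fibroblast list gave DCN higher and FAP lower of 7 tested genes with IFN-beta (0 and 1 over the list alone, adjusted p = 0.692) and COL3A1, FAP and TWIST1 lower with IFN-lambda (3 over the list alone, adjusted p = 0.242, at most 0.309 in camera's alternatives). In fry that list was lower with IFN-lambda (adjusted p = 0.00559). Between the interferons the adjusted p was 0.482 in camera. DCN, a proteoglycan gene of that list, was expressed by untreated cells at 285.4 ± 12.8 CPM. Its change with IFN-beta was 0.09 (0.14 without untreated replicate 1), with an adjusted p of 0.0407 that was 0.206 and 0.0649 without untreated replicates 2 and 3, 0.077, 0.0531 and 0.0847 without IFN-beta replicates 1, 2 and 3, and 0.0538 without IFN-lambda replicate 2 (range over all alternatives 0.00256 to 0.206). The endothelial list (4 genes) gave 0.729, 0.769 and 0.696, and the leukocyte list (6 genes) 0.729, 0.901 and 0.793 as adjusted p in the IFN-beta, IFN-lambda and direct comparisons. KDR, the endothelial gene called, was lower with IFN-beta by a log2 change of -0.40 (SE 0.10), at 21.3 ± 3.17 CPM in untreated, 16.04 ± 1.58 CPM in IFN-beta and 22.2 ± 1.86 CPM in IFN-lambda libraries. CSF1R, a leukocyte list gene, was lower with IFN-lambda at -0.41 (SE 0.09), from 10.01 ± 0.224 to 7.53 ± 0.122 CPM. Of the other leukocyte genes, ITGAX was higher and CORO1A lower with IFN-beta, and CD68 higher and CORO1A lower with IFN-lambda. MITF, of a melanocyte list with 2 tested genes, stood at 25.4 ± 1.33 CPM in untreated cells. IFNE, the endogenous interferon with enough counts to test, was at 0.250 ± 0.108 CPM in untreated and 0.517 ± 0.125 CPM in IFN-beta libraries (adjusted p = 0.0718). It passed without untreated replicate 1 (0.0417) and with the GC and length correction (0.0477, and 0.0352 with the replicate block), in a range of 0.0352 to 0.199.

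**Figure D3:**
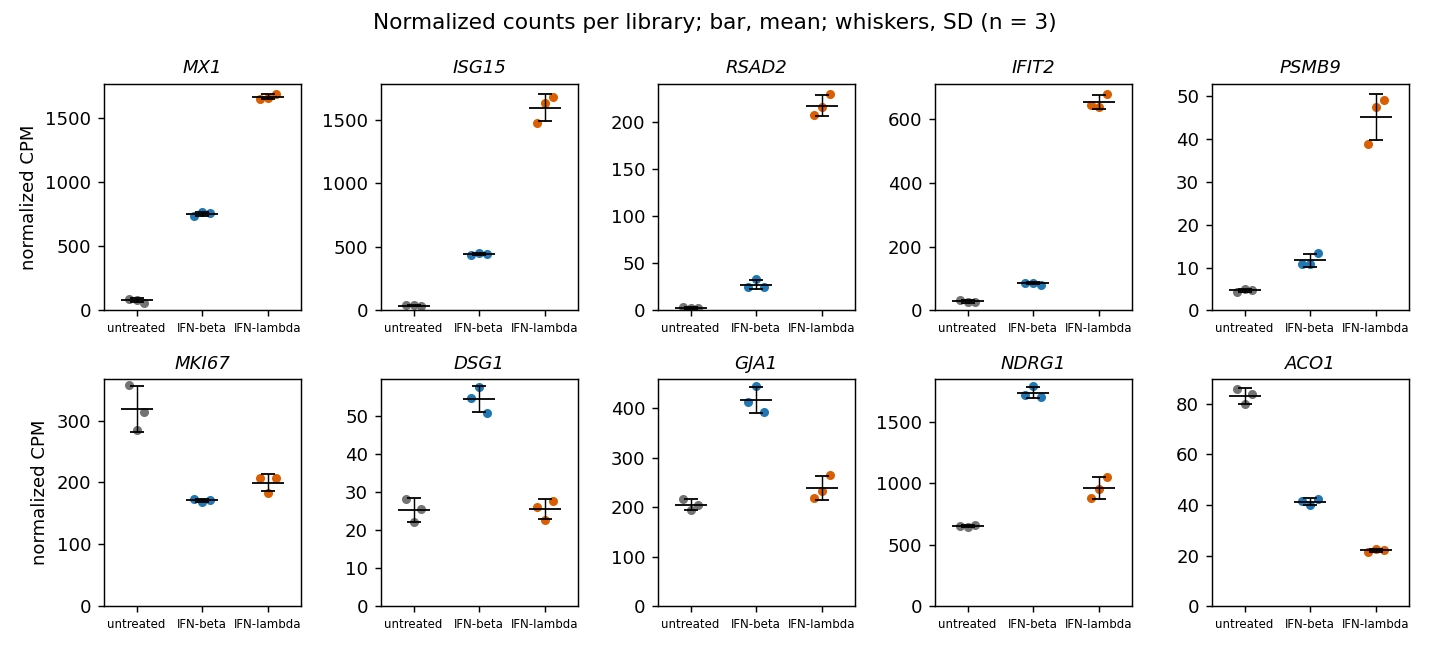
Normalized CPM of 10 genes in each of the 9 libraries, in panels whose linear y axes start at 0, with the 3 groups on the x axis. Points are libraries, the bar is the mean and whiskers are the SD (n = 3); MX1 had means of 77.5, 752 and 1661 CPM in untreated, IFN-beta and IFN-lambda libraries.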

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

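The tests for scaling between libraries, for a mislabelled library and for an exchange of the interferon groups, the correction for GC content and length, and the thinning of the libraries were chosen after the data had been seen.

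Reads with more than 1 alignment, which enter no gene count, made up 30.1% ± 1.4 of the lines in IFN-beta libraries and 27.7% ± 1.0 in untreated ones (SD, n = 3, exact permutation p = 0.1, the smallest possible). IFN-lambda libraries stood at 27.6% ± 2.4. The share with IFN-beta drew attention as a rise over the controls outside the gene counts, and falls were not looked for. Reads in no feature were lower with IFN-lambda (10.4% ± 0.15 against 11.5% ± 0.50 in untreated libraries), without overlap. Ambiguous reads were lower with IFN-beta (1.55% ± 0.06 against 1.65% ± 0.02), also without overlap.

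Other splits of 6 libraries into 3 and 3 are too few, 10 in number, for a share under 0.05. Each split other than the real one also mixes both groups on each side. The difference between the groups then enters the spread within a side, which lowers the number of calls. The counts of these splits therefore cannot tell whether chance gave the calls. With IFN-beta against untreated, 1 of the 10 splits, the real one, called as many genes (5758), and the highest other split called 0 in edgeR (616 at an unadjusted p under 0.05, against 6912 in the real split). With IFN-lambda against untreated, 1 of 10 did (3721), and the highest other called 0 (916 unadjusted, against 5212). Between the interferons, 1 of 10 did (5099), and the highest other called 0 (651 unadjusted, against 6423).

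Antiviral genes were higher with IFN-lambda than with IFN-beta, by a median IFN-beta minus IFN-lambda of -1.08. Scaling between libraries was argued against, since a factor per library moves all genes alike and the list's median minus that of the other tested genes was -1.085. A single mislabelled library was argued against too, since the lowest IFN-lambda library stood 1.17 above the highest IFN-beta library in mean log2-CPM of the list. An exchange of both interferon groups as a whole cannot be told apart from the labelled order, since it would only turn the -1.08 around and no gene in the files is fixed to either interferon. The interferon type and the doses, which the labels do not give, stay open and untested.

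Over all calls, more genes changed with IFN-beta than with IFN-lambda, 1.55 times as many. Most of these changes were small, with 84.8% of the calls with IFN-beta and 83.1% with IFN-lambda under 1.5-fold. Changes of at least 2-fold went the other way, with 230 higher and 31 lower genes with IFN-beta and 291 and 42 with IFN-lambda. Library depth was argued against as the whole cause, since with every library thinned to the smallest the ratio over all calls was 1.61. GC content and gene length were argued against as the whole cause, since with the correction, which also recentred each library, it was 1.43. Leaving out a library gave ratios from 1.26 (without IFN-beta replicate 2) to 1.89 (without IFN-lambda replicate 2). The interferon type, the doses and an exchange of the groups stay open. Library names also number the groups in turn, untreated, then IFN-beta, then IFN-lambda. If that order was kept in handling, its effect cannot be told apart from the treatment in any comparison.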

How the results depend on the processing

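The corrections for GC content and length and the thinning of the libraries were added after the data were seen. Of 183 results of named genes, 148 kept their call and direction in every setting; of their 3645 alternative values, 3509 kept both, 90 fell short of the threshold, 6 newly passed it and 40 changed sign. Counts of called genes, their overlap and the antiviral medians stayed within 1.5 times, or within the replicate SD, except as follows; the cause was not tested unless the setting itself gives it (fewer genes or samples tested, or a stricter threshold).

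With DESeq2, genes at least 2-fold lower were 17 (IFN-beta) and 21 (IFN-lambda), and genes at least 2-fold higher with IFN-beta than IFN-lambda 40. Genes lower with IFN-lambda and not with IFN-beta, and different in the direct test, were 336 there. Without a filter on low counts, genes at least 2-fold lower were 52 and 64, and the correlation of the responses 0.539. With at least 1 CPM in 3 libraries, they were 15 and 19, the direct count 38, the correlation 0.741, and lists lower with IFN-lambda 1. At an adjusted p under 0.01, genes lower with IFN-lambda were 1292 (21 at least 2-fold), and genes higher with IFN-beta than IFN-lambda 1513 (54 at least 2-fold). With the GC and length correction and the replicate block, 1839 genes were lower with both interferons. With an estimated correlation of the genes, lists lower with IFN-beta were 1 and with IFN-lambda 1, and lists higher and lower between the interferons 3 and 5.

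Each library was also left out in turn. Genes lower with IFN-beta and not with IFN-lambda, and different in the direct test, were then 722 (without IFN-beta replicate 2) to 1133. Genes higher with both and more with IFN-beta were 127 (without IFN-lambda replicate 2) to 222. The correlation was 0.678 to 0.729, and lists lower with IFN-lambda were 1 to 2.

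The replicate numbers did not clearly pair the libraries. Same-numbered libraries correlated from -0.142 to 0.276 in their deviations (mean 0.056), and libraries of other numbers from -0.262 to 0.194 (mean -0.027). Of 9 libraries, 2 matched their own number best in both other groups. A weak pairing therefore cannot be excluded. With the replicate block, 5907 genes changed with IFN-beta (5758 without it), 3822 with IFN-lambda (3721) and 5230 between the interferons (5099). Lists lower with IFN-lambda were then 1, oxidative phosphorylation having an adjusted p of 0.0562 in camera (range over its alternatives 0.0157 to 0.469).

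Sign changes of named genes occurred only where they were not called. With IFN-beta, CSF1R was 0.005 with at least 1 CPM (-0.036 to 0.026 leaving out a library), and IFNLR1 0.001 with RLE factors, 0.002 with DESeq2 and 0.013 with at least 1 CPM (-0.049 to 0.031). With IFN-lambda, IFNAR1 was -0.010 with upper-quartile factors and -0.028 with the GC and length correction, with or without the block (-0.009 to 0.034 leaving out a library), and IFNLR1 0.000 without a filter and 0.001 with at least 1 CPM (-0.055 to 0.012). Leaving out a library, KDR ranged from -0.050 to 0.160, MITF from -0.053 to 0.029 and IL10RB from -0.173 to 0.234. Between the interferons, IFNAR2 was 0.006 with the GC and length correction and 0.010 with the block added (-0.156 to 0.053 leaving out a library), and IFNLR1 -0.006 without a filter, -0.033 with the correction and -0.032 with the block added (-0.037 to 0.049). IFNE ranged from -0.182 to 0.208 and IL10RB from -0.086 to 0.321. For lists that were not called, camera's direction turned in some settings, in which the list median did not always change sign. With IFN-beta the leukocyte median was then 0.005 with at least 1 CPM (0.097 with all tested genes), and with IFN-lambda it ranged from -0.099 to 0.030 leaving out a library. Between the interferons the median of receptors and kinases was -0.011 with at least 1 CPM (-0.017 with all tested genes) and -0.038 to 0.009 leaving out a library, that of ER stress genes -0.021 to 0.007 and that of histones -0.035 to 0.075.

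Depth limits genes near the floor of 0.121 to 0.161 CPM, and genes under the filter on low counts were not tested.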

Other observations

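The test of convergent neighbours and its exon overlap check were made after ACO1 and FNDC11 had been seen, and the genes in this part were chosen after their values were seen.

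Several genes of the fixed lists had too few counts for a test, and their raw counts are given for the 3 untreated, 3 IFN-beta and 3 IFN-lambda libraries. IFNL3, an IFN-lambda gene with near-identical copies that make its counts uncertain, had 0 counts in each untreated library and 3 to 5 in each treated library. Its relatives IFNL1 and IFNL2 had 3, 1 and 2 and 2, 1 and 0 counts in the untreated libraries, and 4 to 8 and 1 to 7 in the treated ones. CIITA, the transactivator of MHC class II genes, had 0 counts in each untreated library, 2, 5 and 2 with IFN-beta and 7, 4 and 6 with IFN-lambda. IL6 had 0 counts in each untreated library and 1 to 3 in each treated library. IDO1, a tryptophan-degrading enzyme induced by interferon gamma in many cells, had 0 counts in all 9 libraries, which allows up to 0.121 to 0.161 CPM per library.

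ACO1 fell by 1.92 with IFN-lambda, and its 3′ end on chromosome 9 lies 936 bases from that of DDX58 on the opposite strand, which rose by 4.11. With IFN-beta ACO1 had a log2 change of -1.01 (SE 0.05) and DDX58 one of 2.57. FNDC11, at a mean of only 0.822 CPM, fell by 2.17 with IFN-lambda beside HELZ2, 1378 bases away on the opposite strand. Loss of reads to overlap with the induced gene was argued against, since 0.00% of the exon bases of either gene overlap the neighbour's. A hypothesis is that transcription of the induced neighbour may lower the gene it runs towards: the other 20 convergent neighbours of genes induced at least 4-fold had a median of -0.113, just below the range of -0.101 to 0.066 of 10000 random sets, which were not matched on expression, and 5 of the 20 were called lower and 1 higher. The nearest of these neighbours were divided. NELFE, 3 bases from CFB, was at -0.003, GPATCH11, 34 bases from EIF2AK2, at -0.505, and TMEM132A, 75 bases from SLC15A3, at 0.308 and called higher. The margin of the median below the random range is small, and the strand setting of the counts is not given in the sources used here. A direct effect of IFN-lambda on ACO1 was not tested.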
